A study of Homo sapiens with 3 samples.

How the data were processed

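Expression was measured on 3 two-colour Agilent whole human genome oligonucleotide arrays, 1 for each of the mutant B-RAF melanoma cell lines WM793, WM115 and A375. Per the labels, every array carried RNA from cells induced to make the transcription factor FOXD3, labelled with Cy5 (red), together with RNA from the same line induced to make the control protein LacZ (β-galactosidase), labelled with Cy3 (green). Induction was with 100 ng/ml doxycycline for 5 days. The labels describe high-integrity total RNA that was amplified before dye labelling. The dyes ran the same way on all 3 arrays (0 arrays had them exchanged). Any gene-specific dye effect therefore has the same sign on all 3 arrays and cannot be told apart from an effect of the transgene. The file headers place the 3 arrays on 1 slide and in 1 scan.

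The arrays were quantified with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. The deposited scanner files give the mean intensity of each spot and the median intensity of its local background in both colours, with no normalization, per the file headers. They also hold the Feature Extraction processed intensity, which per the file headers was background-subtracted, detrended and dye-normalized, and the log10 ratio of the red over the green processed intensity. Flags in the same files mark control spots, outlier spots, saturated spots and spots well above background. The deposited series value table holds log2 ratios of red over green. That scale and direction were found by setting each column against the scanner log ratio of the same array, with correlations of 0.9951 for WM793, 0.9976 for WM115 and 0.9982 for A375. The column medians were 0.0026, 4e-04 and -0.0047, so the arrays were centred near 0, but how the authors normalized that table beyond Feature Extraction is not given in the sources used here.

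Each array had 45015 spots, of which 43376 were target spots covering 41000 probes. Signals were corrected with normexp (offset 50) from the mean and local background signals, then normalized within each array by loess with control spots and outlier-flagged spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package at version 1.17.8. Control spots and outlier-flagged spots were then dropped, while saturated spots were kept. Spots of 1 probe were averaged, and the probe with the highest mean brightness stood for a gene. Probe genes were named through their accession or array symbol in the RefSeq gene table of assembly GRCh38, used only for names. Of the probes, 27607 matched (23680 by accession, 2802 by symbol and 1125 by an older symbol) and 13393 kept the name in the files. Coordinates are those in the files, on build hg18. They give the position of the 60-base probe sequence and were not set against an annotation of exons, because none of that build was used here. Probes of closely related genes, such as CYP3A7, the keratins, the HLA genes and HSPA1A, can also bind transcripts of their near-identical relatives.

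A gene was tested if its probe was well above background in at least 1 channel on at least 2 of the 3 arrays and had values on all 3, which left 19708 of 30501 genes. The unit of replication is the cell line (n = 3), and each array's ratio already pairs the transgenes within a line. Log2 ratios of FOXD3 over LacZ were fitted with limma's lmFit and eBayes, intercept only, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The p-values measure the spread between the 3 lines. A size rule without a p-value counted genes at least 2-fold higher, or at least 2-fold lower, in all 3 lines. Within a line there was 1 array, so counts per line have no replicate check. The 27 gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists. Where a probe was not well above background in 1 channel on any array, a bound is given as "at least N-fold", from single-channel values after Aquantile normalization with the dim channel set to no less than the lowest signal among probes well above background. A bound of this kind applies to the mean over the 3 arrays and not to each line. It is open to dye bias, because the dyes were not exchanged. Where the red channel was saturated on all 3 arrays no fold is given, because the ratio of such a spot depends on the normalization, and its range over the alternatives or the values of other probes stand in the text instead.

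The number of arrays limits the precision, and so does the signal over background. Between 60.9% and 65.3% of target spots in a channel were well above background. Negative control spots had median intensities of 518.1 to 573.2 in green and 1034.1 to 1042.9 in red, against local backgrounds of 59 to 64. Normexp left them at 263.6 to 291.6 in green and 542.3 to 556 in red. Ratios of dim genes are therefore compressed towards 0 in the main values, and the Feature Extraction log ratio, which subtracts more, gives larger ratios for the same genes. In red, 170 to 215 spots per array were saturated, and in green 0.

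The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The genes named are FOXD3, all tested members of the list of ERBB receptors and ligands, the 12 genes with the largest positive and the 12 with the largest negative mean log2 ratio among those passing limma with 1 sign on all arrays, the 5 highest and 5 lowest genes of each line, up to 4 members of each list with the largest mean ratio in size, and list members passing over all genes. Because no gene passed, the 2 sets of 12 were filled, as the rule provides, with genes at least 2-fold in 1 direction in all 3 lines, ranked by their smallest ratio. The rule passes over LOC numbers, accessions and open reading frame labels. Other list members are named where they passed when adjusted over the list alone, and genes named outside the rule are said to be. That adjustment does not allow for the number of lists, and 17 of the 27 lists had such a member. Some genes that the rule takes are not reported here.

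The fit was tested on simulated data with 19708 genes on 3 arrays. Of 100 genes simulated at 2-fold limma called 27, of 100 at 4-fold it called 65, and it made 2 false calls among 19508 unchanged genes. The size rule found 8 of the 100 genes at 2-fold and 96 of the 100 at 4-fold, with 16 false calls. The changed genes were drawn at random and shifted by the same amount on all 3 arrays, so these rates need not hold for the real arrays. Camera called 0 of 26 lists when none was shifted and 1 when 1 was shifted. The simulated genes varied independently of each other, so this does not check camera on lists of correlated genes. The alternatives were no background correction, normexp with offset 16, the Feature Extraction log ratio, the series value table, median centring in place of loess, scale normalization between arrays, no filter or a strict filter on dim probes, the mean of a gene's probes, each line left out, other thresholds, eBayes with trend and robust, a fit of single channels without pairing, camera with an estimated correlation, and fry. A correction for probe GC content was chosen after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.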

Results

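The series compared melanoma cells made to express FOXD3, a forkhead transcription factor of the neural crest lineage, with the same cells making LacZ. Its title sets the question of whether FOXD3 raises ERBB3, a receptor of the epidermal growth factor receptor family, as part of the response to RAF and MEK inhibitors. No inhibitor-treated sample is among the arrays analysed here. The data are 3 arrays, 1 each for WM793, WM115 and A375, which are established human melanoma lines with mutant B-RAF. All values below are log2 ratios of FOXD3 over LacZ, so that positive values mean more signal in FOXD3 cells. Median spot intensities were 809.5 to 889.7 in the LacZ channel and 1757.2 to 1902.4 in the FOXD3 channel.

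The probe for FOXD3 itself, at chromosome 1:63562470-63562529 (hg18), differed little between the channels. Its log2 ratio was 0.46 in WM793, -0.06 in WM115 and 0.26 in A375, a mean of 0.22 ± 0.26 (SD, n = 3), or 1.16-fold (limma, adjusted p = 0.379). The probe was bright in LacZ cells too, at percentiles 87.4, 92.2 and 90.5 of all probes in WM793, WM115 and A375, and its sequence is 85% GC against a median of 41.7%. Whether the probe lies within the transgene is not given in the sources used here, so this measurement does not check the labels. With median centring in place of loess the mean was 0.73 (adjusted p = 0.059).

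ERBB3 was higher in FOXD3 cells of WM793 (0.89) and WM115 (0.60) and close to equal in A375 (-0.07), as measured by the brightest probe, at chromosome 12:54782427-54782486. The mean of 0.47 ± 0.50 (SD, n = 3), or 1.39-fold, did not exceed the spread between lines (limma, adjusted p = 0.284). The other ERBB3 probes gave 1.56, 0.83 and 0.47, and 0.75, 0.53 and 0.17, in WM793, WM115 and A375, so both were higher in all 3 lines. The array assigns each of them to a different ERBB3 transcript record from that of the brightest probe. They may therefore report other forms of the transcript, which was not tested. ERBB2, the usual dimerization partner of ERBB3, followed a similar order, with 0.39, 0.42 and -0.05, though its other, dimmer probe had a mean of -0.02. NRG2, which encodes a neuregulin ligand, was higher in all 3 lines at 2.02, 0.79 and 0.23 (mean 1.01 ± 0.92). HBEGF, a ligand of the epidermal growth factor receptor, was also higher in all 3 lines, at 0.71, 0.32 and 0.63 (mean 0.55 ± 0.21), and passed when adjusted over the list alone (adjusted p = 0.0363). Its other probe, of about the same brightness, did not bear this out, with a mean of 0.03. The largest difference in the family was in ERRFI1, which encodes a feedback inhibitor of ERBB receptors. It was 4.35-fold lower in FOXD3 cells by its brightest probe, with log2 ratios of -2.72, -1.40 and -2.24 (mean -2.12 ± 0.67), and passed when adjusted over the list alone (adjusted p = 0.0143) but not over all genes (adjusted p = 0.119). The other, dimmer ERRFI1 probe was lower by less, at -1.93, -0.32 and -1.19 in WM793, WM115 and A375 (mean -1.15). The ligand genes NRG1 (mean -0.48 ± 0.78), AREG (-0.18 ± 0.77) and BTC (0.06 ± 0.18) lay within the spread between lines. Of the 8 tested members of the list, 2 were higher and 1 was lower in all 3 lines, and camera did not call the list (adjusted p = 0.659). Its median was 0.155, its mean -0.053. The ERBB3 call depended on the normalization, with a mean of 1.08 under median centring (limma, adjusted p = 0.0473) and adjusted p between 0.0473 and 0.623 over the alternatives.

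**Figure D1:**
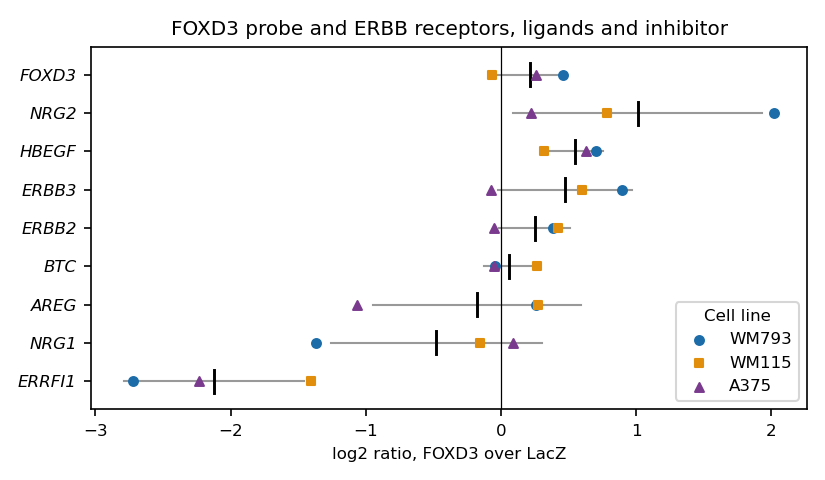
Log2 ratio of FOXD3 over LacZ (horizontal axis) for FOXD3, the tested ERBB receptors and ligands, and ERRFI1, each by its brightest probe. Dots are single lines, black ticks the mean and grey bars the mean ± SD over 3 lines, with ERRFI1 at -2.12 lying apart from the receptors and ligands and ERBB3 at 0.47 with a bar that spans 0.

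Across all genes, 41 were at least 2-fold higher and 82 at least 2-fold lower in FOXD3 cells of all 3 lines. The highest included PDE8B, a cyclic AMP phosphodiesterase, at 8.14-fold (mean 3.02 ± 0.58, n = 3), and the chemokine CXCL14 at 7.52-fold (2.91 ± 0.78). NGFR, the low-affinity nerve growth factor receptor and a neural crest marker, was 3.84-fold higher with little spread (1.94 ± 0.15; chromosome 17:44946977-44947036). KIRREL3, an adhesion protein of the immunoglobulin superfamily, was 4.72-fold higher. The cytokine IL1B was 4.18-fold higher and the sialomucin PODXL 6.03-fold higher, the latter with 2.20, 4.12 and 1.46 in WM793, WM115 and A375. TTR, which carries thyroid hormone, was 5.20-fold higher, the collagen COL15A1 3.86-fold, OLFML3 3.97-fold, the sorting receptor SORL1 3.87-fold and the membrane-type metalloproteinase MMP15 2.94-fold. PDE8B, KIRREL3 and TTR were well above background in LacZ cells on 2 of 3 arrays, so their folds hold only for the main values. Over the alternatives their log2 means ran from 2.45 to 4.60, from 1.13 to 3.15 and from 2.00 to 3.23. The other probes of COL15A1, OLFML3 and MMP15 were higher too but by less, with means of 1.03, 1.01 and 1.06. CYP3A7 had 4.45, 2.74 and 1.66 by a probe that can also bind other CYP3A transcripts, and that was well above background in FOXD3 cells on 2 arrays and in LacZ cells on 1. The Feature Extraction log ratio of CYP3A7 in A375 was 0, so no fold is given.

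Among the genes lower in all 3 lines, HMCN1, an extracellular matrix protein, was 5.62-fold lower (-2.49 ± 0.08, n = 3; chromosome 1:184426302-184426361). SGK1, a serum- and glucocorticoid-regulated kinase, was 5.25-fold lower (-2.39 ± 0.28; chromosome 6:134532349-134532408). OSBPL10, of the oxysterol-binding protein family, was 5.21-fold lower and CEMIP, which takes part in hyaluronan breakdown, 5.11-fold lower. The transcription factor SALL4 was 3.74-fold lower and the orphan nuclear receptor NR0B1 4.27-fold lower. The adenosine receptor gene ADORA2B gave -1.66, -1.67 and -1.66, and RPS6KA3, a ribosomal S6 kinase that ERK activates, was 3.69-fold lower. CSGALNACT1, AGMO, NIBAN1 and CNTNAP3 were 4.44, 4.60, 4.43 and 4.13-fold lower. These folds are by the brightest probe. Other measured probes were lower too but by less, with means of -0.56 for HMCN1, -0.57 for CSGALNACT1 and -0.76 for CNTNAP3. Those of NIBAN1, OSBPL10, RPS6KA3 and CEMIP had -0.91, -1.08, -1.29 and -1.51.

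None of these genes passed limma's test over all 19708 genes (0 past the threshold, smallest adjusted p = 0.118), where 4458 had an unadjusted p under 0.05 (2042 higher and 2416 lower) against 985 that chance would give. Limma with trend and robust settings also called 0 genes, with a smallest adjusted p of 0.239. For the size rule, 123 genes were 2-fold in 1 direction in all 3 lines, against 0.249 higher and 0.398 lower expected if the lines were independent, and 11 genes were 2-fold in all 3 lines with mixed signs. In pairs of lines the same rule was met by 187 genes without WM793, 274 without WM115 and 381 without A375. The counts depend on the normalization: under median centring limma called 1809 genes, 1646 of them higher, and the Feature Extraction log ratio gave 426 genes 2-fold in all 3 lines. Dye and transgene were not separated by the design, so a gene-specific dye effect would have the same sign on all 3 arrays.

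**Figure D2:**
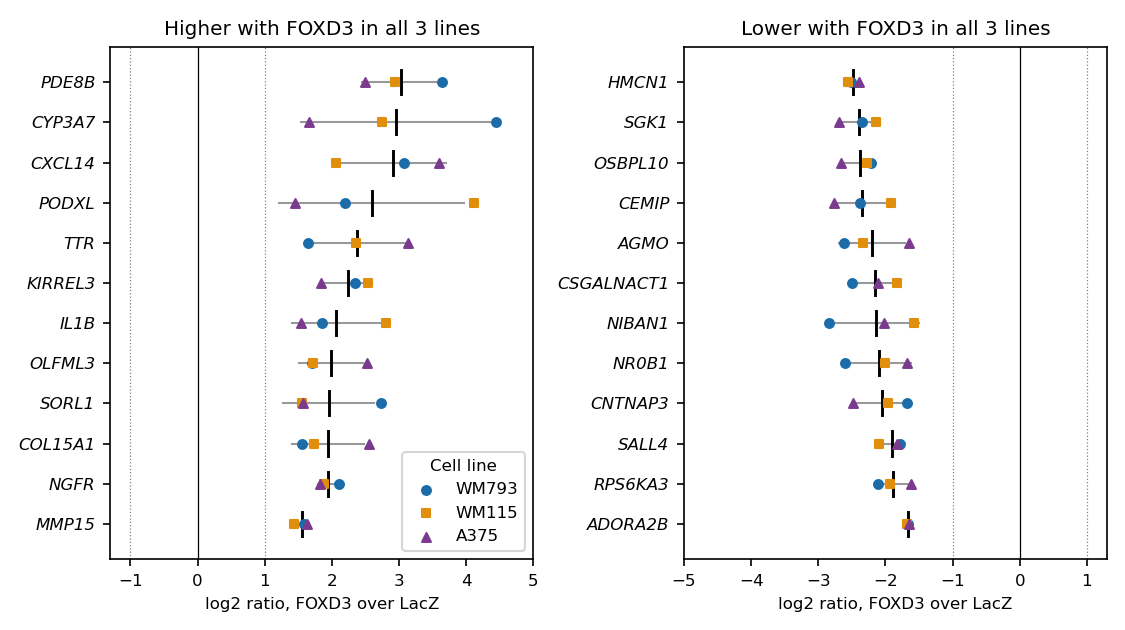
Log2 ratio of FOXD3 over LacZ (horizontal axis) for the 12 higher and 12 lower genes taken by smallest ratio over the 3 lines, each by its brightest probe. Dots are single lines, black ticks the mean, grey bars the mean ± SD over 3 lines, and dotted lines mark 2-fold; NGFR at 1.94 ± 0.15 and HMCN1 at -2.49 ± 0.08 are among those with narrow spread.

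Genes of cell division were lower in FOXD3 cells, most of all in WM793. In the list of G2 and mitosis genes the median log2 ratio was -1.50 in WM793, -0.39 in WM115 and -0.41 in A375, and 20 of 22 genes were lower in all 3 lines. Over the lines the list's median of -0.79 came to -0.244 under median centring and -0.405 without WM793. The list fell by camera (adjusted p = 1.26e-05), a call lost with an estimated correlation (adjusted p = 0.833), where the correlation between members was estimated at 0.953, and by directional fry (adjusted p = 0.366). The cyclin CCNB1 had a mean of -1.05 ± 0.46, the mitotic kinase TTK -1.11 ± 0.57 and the kinetochore motor CENPE -1.11 ± 0.72 (n = 3). CENPF had -1.07 ± 0.65, but its mean turned to 0.07 under median centring, and that of CCNB1 came to -0.21. Genes of DNA replication and of the G1 to S transition fell too (camera, adjusted p = 0.00326), with medians of -1.0, -0.14 and -0.10, and 13 of 22 genes were lower in all 3 lines. That call was lost with an estimated correlation (adjusted p = 0.833; correlation 0.858), by directional fry (adjusted p = 0.429), without WM793 (adjusted p = 0.0869) and under median centring (adjusted p = 0.34). TYMS, which makes thymidylate, had a mean of -1.21 ± 0.74, the clamp loader gene RFC3 -0.86 ± 0.26, the licensing factor CDT1 -0.73 ± 0.67 and CDC45 -0.70 ± 0.82, where median centring brought TYMS to -0.33 and CDC45 to -0.05. No member of either list passed when adjusted over the list alone. Among 20 CDK inhibitors and p53 targets, CDKN1A, which encodes the CDK inhibitor p21, was higher in all 3 lines by its brightest probe (0.92 ± 0.26). It was the 1 member to pass when adjusted over the list alone (adjusted p = 0.0482). The other CDKN1A probe gave 0.79, 0.34 and 0.00 in WM793, WM115 and A375, so it did not bear out a rise in A375. CDKN1C was high in WM793 (3.42) and WM115 (2.49) but not in A375 (-0.52), GDF15 had a mean of 0.96 ± 1.13 and CDKN2C -1.18 ± 1.08. Camera did not call that list (adjusted p = 0.7).

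Several genes that ERK signalling induces were lower in FOXD3 cells. SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, had log2 ratios of -2.43, -1.70 and -1.46 (mean -1.86 ± 0.50, n = 3), and PHLDA1 had -1.67 ± 0.84. These 2 genes, the transcription factor gene ETV5 (-0.76 ± 0.25) and the phosphatase gene DUSP4 (-0.67 ± 0.23) were the 4 lower members past the threshold when adjusted over the list alone, DUSP4 turning to 0.01 under median centring, where ETV5 had -0.37 and SPRY2 -1.15. EPHA2 (0.71 ± 0.09) was the 1 higher member. ETV1 had a mean of -1.0 ± 0.68 and EPHA4 -1.64 ± 1.70. The list of 20 was not called (camera, adjusted p = 0.32), and its median of -0.215 turned to 0.085 under median centring. In the PI3K and AKT list, 4 of 21 members were lower when adjusted over the list alone. Among them were SGK1, the phosphatase gene INPP4B (-1.27 ± 0.35) and PDK1 (-1.19 ± 0.05, n = 3), which under this symbol encodes a kinase of pyruvate dehydrogenase in glucose metabolism and not a kinase of the AKT pathway. PIK3R3 had a mean of 1.01 ± 0.97. The list was not called (adjusted p = 0.145), and its median of -0.152 turned to 0.005 under median centring. Counts over the list alone are not particular to these pathways: of 14 housekeeping controls, 3 were higher and 2 lower by that measure. Of 26 receptor tyrosine kinases outside the ERBB family none passed over the list alone and camera gave an adjusted p of 0.785. Besides ALK, the largest means on this list, which does not hold EPHA4, were -1.90 ± 1.21 for EPHA3, 1.51 ± 1.01 for MERTK and -1.24 ± 1.37 for MET. ALK was at least 2.17-fold higher as a bound over the lines, with log2 ratios of 1.80, 1.98 and 0.24 in WM793, WM115 and A375.

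**Figure D3:**
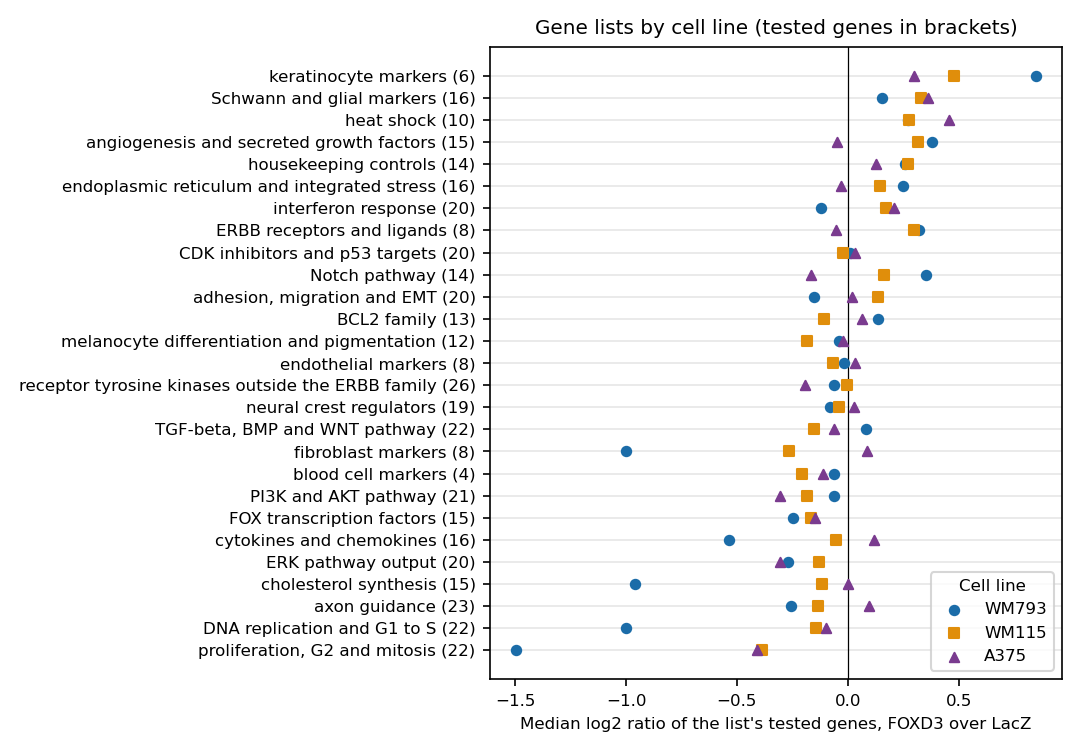
Median log2 ratio of FOXD3 over LacZ over the tested members of each gene list (horizontal axis), with 1 dot per line and the number of tested members in brackets. The G2 and mitosis list stands at -1.50 in WM793 against -0.39 and -0.41 in WM115 and A375.

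Neural crest and glial genes moved in part. Of 19 neural crest regulators, NGFR and the transcription factor gene ETS1 (0.66 ± 0.20) were higher, and TWIST1 was lower (-1.37 ± 0.64, n = 3), when adjusted over the list alone. SOX8 had 3.60, 1.5 and 0.41 by its brightest probe but 0.05, -0.35 and -0.41 by its other one, and TFAP2B, well above background on 2 arrays, had -0.02, -1.16 and -2.55; neither passed. The list as a whole was not called (camera, adjusted p = 0.99, direction down), with a median of -0.052 that turned to 0.129 under median centring, and a mean of 0.081. Schwann cell and glial markers rose by camera (adjusted p = 0.0356), with medians of 0.16, 0.33 and 0.36 in WM793, WM115 and A375, and 9 of 16 genes were higher in all 3 lines. The call was lost in 7 alternatives: with an estimated correlation (adjusted p = 0.833), by directional fry (adjusted p = 0.0571), without A375 (adjusted p = 0.0794), under median centring (adjusted p = 0.34), with the series value table (adjusted p = 0.12), with the Feature Extraction log ratio (adjusted p = 0.0798) and with the mean of probes (adjusted p = 0.0733). The list's median over the lines, 0.358 in the main values, ran from 0.259 to 0.574 over the alternatives. The myelin gene CNP (1.34 ± 0.40) and the calcium-binding protein gene S100B (0.76 ± 0.19) were among those that passed when adjusted over the list alone, though the other CNP probe gave -0.04, 0.29 and 0.62. GJB1 had a mean of 1.15 ± 0.71 and GAP43 0.85 ± 0.76. GAP43 was well above background in LacZ cells on 1 array and in FOXD3 cells on 2, and its mean ran from 0.50 to 1.72 over the alternatives. CDH19, a cadherin of Schwann cell precursors, did not pass, with -3.15, -1.19 and -0.20 by its brightest probe and -1.28, -0.54 and 0.41 by its other one. Of 12 melanocyte and pigmentation genes none passed over the list alone. MITF, the master regulator of melanocytes, had -0.71, -1.84 and -0.42 by its brightest probe (mean -0.99 ± 0.75). Its other measured probes gave -0.79, -2.56 and -0.11, and 0.05, -1.07 and 0.26, in WM793, WM115 and A375. MREG had a mean of -0.71 ± 0.94, ACP5 0.84 ± 0.34 and the melanosome protein gene PMEL 0.49 ± 0.36. That list was not called (adjusted p = 0.99, direction down), with a median of 0.01 and a mean of -0.032.

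Developmental signalling genes went both ways. In the Notch list of 14, the Notch target HES1 (1.48 ± 0.32, n = 3), NOTCH4 (0.78 ± 0.36) and NOTCH1 (0.34 ± 0.08) were higher, and NOTCH2 (-0.92 ± 0.26) and HES4 (-0.52 ± 0.16) lower, when adjusted over the list alone; NOTCH2 turned to 0.05 under median centring, and the other NOTCH4 probe was lower in all 3 lines (mean -0.34). HEY1 had -0.55, 0.62 and 2.41. In the TGF-beta, BMP and WNT list of 22, the WNT effector LEF1 (-1.60 ± 0.33) and the receptor gene FZD7 (-0.94 ± 0.20) were lower and WNT3 (0.73 ± 0.12) was higher by the same measure, and DKK3 and TCF7 had means of 1.06 ± 1.13 and 0.95 ± 0.52. The other, dimmer LEF1 probe was lower by much less, with a mean of -0.23. In the list of 23 axon guidance genes, ROBO1 (-1.66 ± 0.10) and SEMA3A (-1.39 ± 0.40) were lower, and SEMA3C had a mean of -1.13 ± 1.02. UNC5B was at least 2.37-fold higher as a bound over the lines, with 1.54, 3.18 and 0.24 in WM793, WM115 and A375. Of 15 other forkhead genes, FOXC1 was lower (-1.62 ± 0.14; -0.74 with the mean of its probes) and FOXK1 higher (0.56 ± 0.05; 0.10 by its other probe) when adjusted over the list alone, and FOXF1 and FOXP1 had means of 0.71 ± 1.05 and 0.57 ± 0.95. Camera called none of these lists, with adjusted p of 0.772 for Notch, 0.858 for TGF-beta, BMP and WNT, 0.515 for axon guidance and 0.166 for the forkhead genes, though the axon guidance list passed, direction down, under median centring (adjusted p = 0.048). The medians of the TGF-beta list (-0.067) and the forkhead list (-0.198) turned to 0.102 and 0.146 under median centring.

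Genes of adhesion and secretion were also mixed. In the adhesion, migration and EMT list of 20, RND3, a small GTPase that opposes RhoA signalling, was lower at -3.00, -1.16 and -1.91 (mean -2.02 ± 0.93, n = 3), as was the matrix gene TNC (-0.98 ± 0.15), which came to -0.02 under median centring. SPARC was higher, but its red signal was saturated on all arrays and its log2 mean ran from 0.64 to 2.79 over the alternatives, so no fold is given. These 3 genes passed when adjusted over the list alone, and THBS1 had a mean of 1.29 ± 1.28. Among 15 angiogenic and growth factor genes, PDGFA (1.03 ± 0.31) and FGF1 (0.63 ± 0.20) were higher and VEGFB (-0.72 ± 0.28) lower by the same measure, VEGFB turning to 0.31 under median centring. ANGPTL4 was high in WM793 (2.54) and WM115 (2.19) and not in A375 (-0.15), IGFBP5 likewise (2.72, 2.26 and -0.80), and ANGPT1 had a mean of -0.92 ± 1.25. Among 16 cytokine genes, IL1B was higher and CXCL2 lower (-1.10 ± 0.29) when adjusted over the list alone. CXCL1 had -3.07, -3.49 and -0.94, CXCL8 -3.91, -2.02 and 0.42, and CCL2 -1.19, 2.42 and 3.97. The interferon list of 20 had no member past the threshold over the list alone, and IFIT2 was high in A375 (2.59) but not in WM793 (-0.15) or WM115 (-0.06). IFIT3 likewise had 0.19, 0.04 and 1.65, MX2 a mean of 0.61 ± 0.50 and IFIH1 -0.65 ± 1.14. Camera called none of these 4 lists, with adjusted p of 0.886 for adhesion, 0.422 for angiogenesis, 0.772 for cytokines and 0.229 for interferon. The cytokine median of -0.204 turned to 0.019 under median centring, and without WM793 the interferon list passed (adjusted p = 0.0215).

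Heat shock genes rose as a list (camera, adjusted p = 0.00624), with medians of 0.27, 0.27 and 0.46 in WM793, WM115 and A375. The call was lost with an estimated correlation (adjusted p = 0.833), by directional fry (adjusted p = 0.0797), without A375 (adjusted p = 0.0701), with the Feature Extraction log ratio (adjusted p = 0.125) and with the series value table (adjusted p = 0.32). Over the lines the list's median of 0.338 ran from 0.062 with the series value table to 1.457 under median centring. HSPA8 was higher with a saturated red signal, HSPA1A had a mean of 0.74 ± 0.07 and DNAJB1 0.54 ± 0.02 (n = 3), and these were the 3 of 10 members past the threshold over the list alone. HSPD1 had a mean of 0.40 ± 0.31, which turned to -0.01 with the series value table. HSPA8 ran from 0.07 to 2.36 over the alternatives, so no fold is given. The other HSPA8 probes had means of 0.84, 0.85 and -0.31, and the other HSPD1 probe -0.16. The 16 genes of the endoplasmic reticulum and integrated stress responses had no member past the threshold and were not called (adjusted p = 0.259), though they passed under median centring (adjusted p = 0.000688). HERPUD1 had a mean of 1.13 ± 1.02, HSP90B1 had a saturated red signal by its brightest probe and a mean of 0.51 by its other one, and PPP1R15A and ATF3 had means of 0.41 ± 0.25 and 0.40 ± 0.25. Of 15 cholesterol synthesis genes, FDFT1, which encodes squalene synthase, was lower at -1.15, -1.09 and -1.15 and passed over the list alone (adjusted p = 0.00239). DHCR7 had a mean of -0.91 ± 0.65 and INSIG1 -0.65 ± 0.64. Under median centring FDFT1 came to -0.42 and DHCR7 to -0.06. The cholesterol list had medians of -0.96, -0.12 and 0.00 in WM793, WM115 and A375 (camera, adjusted p = 0.0511), and it passed without WM115 (adjusted p = 0.0043), without A375 (adjusted p = 0.0255), without background correction (adjusted p = 0.0414) and with the strict filter (adjusted p = 0.044). Without WM793 its median was 0.021 (adjusted p = 0.608), under median centring 0.134 (adjusted p = 0.792), and with an estimated correlation the adjusted p was 0.833. Among 13 BCL2 family genes none passed. The proapoptotic PMAIP1 had a mean of -1.43 ± 0.87, BCL2L2 -0.78 ± 0.52, BCL2 -0.66 ± 1.06 and BOK 0.71 ± 0.71 (-0.28 by its other probe), and the list was not called (adjusted p = 0.874), with a median of 0.014 and a mean of -0.104.

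Markers of other cell types showed no list-wide shift that passed. Fibroblast markers had medians of -1.0, -0.27 and 0.09 in WM793, WM115 and A375 (camera, adjusted p = 0.772), with means of -1.27 ± 1.26 for FAP, -1.01 ± 0.99 for LOX, 0.61 ± 0.53 for COL1A1 and 0.32 ± 1.41 for LUM (n = 3). The list's median of -0.075 turned to 0.153 under median centring. Of 6 tested keratinocyte markers, KRT14 was higher (1.26 ± 0.57) and passed over the list alone, KRT17 was at least 1.4-fold higher, KRT16 had 2.15, 0.51 and -0.21, and TP63 -1.90, 0.45 and 0.38 (camera, adjusted p = 0.145; 0.0215 without WM793). Endothelial markers had medians of -0.01, -0.07 and 0.03 (adjusted p = 0.99), with a mean of -0.47 ± 0.14 for SOX18, 0.45 ± 0.47 for VWF, 0.39 ± 0.33 for CLDN5 (-0.39 by its other probe) and -0.08 ± 0.07 for ROBO4. Only 4 of 12 blood cell markers were measurable, too few for camera, with a list mean of 0.054 against a median of -0.144. They were CD68 (0.74 ± 0.54), HBA1 (-0.24 ± 0.03), LCP1 (-0.18 ± 0.18) and CD79A (-0.11 ± 0.17, turning to 0.00 under median centring). The 14 housekeeping controls were not level. RPLP0, ACTB (0.69 ± 0.34) and SDHA (0.40 ± 0.11) were among those higher and PGK1 among those lower when adjusted over the list alone. PGK1 (-0.42 ± 0.09) turned to 1.02 under median centring, and ACTB to -0.02 with the mean of its probes. RPLP0, whose red signal was saturated, ran from a log2 mean of 0.09 to 2.40 over the alternatives. PPIA was saturated in red as well, and its other probes had means between -0.03 and 0.76. The housekeeping list was not called with loess (camera, adjusted p = 0.145) but passed under median centring (adjusted p = 4.02e-05).

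WM793 had the most genes that differed. At least 2-fold differences numbered 906 higher and 958 lower of 19938 measured genes in WM793, 426 and 413 of 20002 in WM115, and 343 and 453 of 19370 in A375. In WM793 the highest values included those for CYP3A7 (4.45), PDE8B (3.64) and SOX8 (3.60), and for KLK7, which was measurable only in FOXD3 cells of that line and over the lines was at least 1.3-fold higher. The lowest were CXCL8 (-3.91), FZD1 (-3.64), SLITRK6 (-3.41) and SCARA5 (-3.32), with GBA3 at least 1.16-fold lower by a similar bound. In WM115 the highest were PODXL (4.12), SLC14A1 (3.77), HLA-DOA (3.51), OLFML2A (3.23) and HLA-DQA2 (3.21). The lowest there were CXCL1 (-3.49), TMTC1 (-2.96), the transcription factor gene SOX2 (-2.88), TKTL1 (-2.80) and HS6ST2 (-2.79). In A375 the plasminogen activator inhibitor gene SERPINB2 reached 5.42, followed by MYOZ2 (4.16), CCL2 (3.97) and SCRG1 (3.70), and MMP12 was at least 1.49-fold higher as a bound over the lines. The lowest in A375 were RIPOR2 (-3.52), FGF13 (-3.50), the glutamate transporter gene SLC1A1 (-3.42), EPHA4 (-3.20) and EPHA3 (-3.09). HLA-DQA2 and CYP3A7 were well above background in LacZ cells on 1 array and SLC14A1, MYOZ2 and SERPINB2 on 2, CXCL8 in FOXD3 cells on 1 and EPHA4 and RIPOR2 on 2. The sizes and order hold only for the main values: over the alternatives SLC14A1 in WM115 ran from 1.93 to 7.39, HLA-DQA2 in WM115 from 1.5 to 6.61 and MYOZ2 in A375 from 2.70 to 6.52. Other probes often gave smaller sizes, with 0.02 for SCARA5, -1.07 for FZD1 and 0.05 for SOX8 in WM793. Another HLA-DOA probe gave 1.43 in WM115 and another SERPINB2 probe 1.28 in A375, while the other TMTC1 probes gave -2.14 and -1.89 in WM115. With 1 array per line these differences have no replicate check, and differences between lines were not tested.

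The 3 lines moved together in part. Across the 19708 genes, Pearson's r of the log2 ratios was 0.556 between WM793 and WM115, 0.43 between WM115 and A375 and 0.343 between WM793 and A375, with Spearman's rho of 0.551, 0.456 and 0.315. Genes are not independent replicates, and all arrays share the dye orientation, so no p is given. In all, 9929 genes (50.4%) had the same sign in all 3 lines, where independent lines would give 25%. Of the 2478 genes at least 2-fold in some line, 1837 were so in exactly 1 line and 507 in exactly 2.

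**Figure D4:**
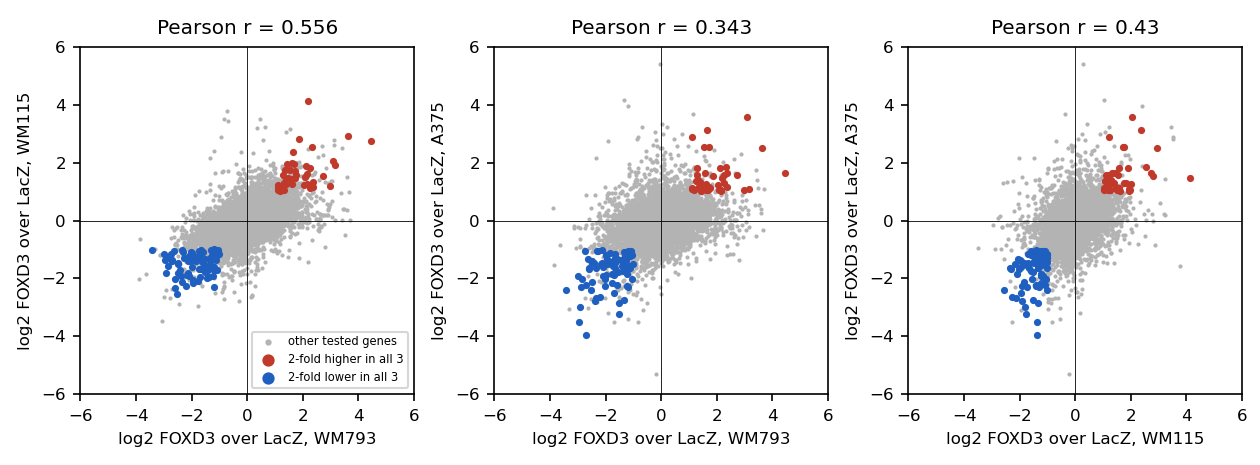
Log2 ratios of FOXD3 over LacZ in 1 line against another for the tested genes, in 3 panels, 1 for each pair of lines. Genes 2-fold in all 3 lines are in red (41 higher) and blue (82 lower), and Pearson's r runs from 0.343 to 0.556.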

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

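In this part, the tests of GC content, of the sign patterns of the 2-fold count, of exchanged dyes, of the proliferation list, and of the FOXD3 probe's pedestal and construct were chosen only after the result was seen.

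Far more genes were 2-fold in 1 direction in all 3 lines (123) than in any mixed sign pattern. As the whole cause, a dye effect tied to single probe sequences is argued against by other probes of the same genes. For the 46 genes with another measured probe, its ratio in the gene's direction had a median of 0.88 (quartiles 0.58 to 1.12). The direction was the same for all 46. The brightest probes of these genes had a median of 1.62 in size. A partial effect of single probes therefore stays open, as does compression of the dimmer probes. Over 5153 genes with paired probes, covariance between lines across probes was 0.66 of that within 1 probe (0.63 to 0.68 over 1000 bootstrap draws). Probe GC content is argued against as well, since 118 of the 123 genes stayed 2-fold in all 3 lines after its correction. The remaining 77 genes had no other measured probe, and a dye effect shared by all probes of a gene cannot be told apart from FOXD3, because 0 arrays had the dyes exchanged. The 3 arrays allow only 4 sign patterns, too few for a share under 0.05: limma called 0 genes in all 4 patterns, while 1 pattern, the real one, had 123 genes at 2-fold and the highest other had 4.

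In the G2 and mitosis list, all 22 genes were lowest in WM793. Among 10000 random lists matched on brightness the lowest WM793 median was -0.64, against -1.50 for the list. This cannot decide whether probe brightness plays a part, because loess had already removed the trend of ratio with brightness. Under median centring, which leaves that trend in place, the list's median over the lines came from -0.79 to -0.244. A dye effect of single probes that differed between arrays stays open. Only 4 of the genes had another measured probe, too few to decide, and for these the WM793 ratio minus the mean of the other lines had a median of -0.88 (quartiles -1.02 to -0.52) and was negative for 3 of the 4. The other 18 had no other measured probe. A biological hypothesis is that FOXD3 may slow the division of WM793 cells more than of the others, but with 1 array per line a difference in culture density or timing between the FOXD3 and LacZ cells of that line stays open and was not tested.

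The FOXD3 probe lay near 0 in cells induced to make FOXD3. Background left under dim spots is argued against, because the Feature Extraction signals, which subtract more, gave a mean of 0.33 ± 0.27 (SD, n = 3), under the 1 that was set as the least such background would have hidden. Binding of other transcripts to a GC-rich sequence may contribute: the 183 probes of at least 75% GC had a median brightness percentile of 80.1 in LacZ cells (quartiles 60.4 to 97.4), which only just meets the bound set in advance. The alternative that the probe's sequence is absent from the construct stays open, since the construct is not described, and the mean of 0.22 would fit either. No biological explanation was tested.

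The lines differed by at least 2-fold in opposite directions for 4 of the 155 genes named by the rule, a difference that was not tested because each line has 1 array. MYOZ2 was 5.52 log2 units higher in A375 (4.16) than in WM793 (-1.35) by its brightest probe. Its other probe gave 1.24 in A375 and 0.09 in WM793, so the opposite signs rest on 1 probe. That other probe was well above background on 2 arrays in FOXD3 cells and on 0 in LacZ cells. SLC14A1 was 5.34 units higher in WM115 (3.77) than in A375 (-1.57). CCL2 was 5.16 units higher in A375 (3.97) than in WM793 (-1.19). LUM was 2.79 units higher in A375 (1.62) than in WM793 (-1.17). MYOZ2 was well above background on 2 of 3 arrays in either channel and SLC14A1 on 2 of 3 in LacZ cells, so their sizes are not fixed: over the alternatives MYOZ2 in A375 ran from 2.70 to 6.52 and SLC14A1 in WM115 from 1.93 to 7.39.

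Negative control spots, which match no human transcript by design and entered no comparison, were brighter than the local background around them. In green the ratio of spot to local background was 8.78 in WM793, 9.47 in WM115 and 9.18 in A375. In red it was 16.27, 16.68 and 16.82.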

How the results depend on the processing

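The GC correction was chosen after seeing the data, and it gave 126 genes at 2-fold in all 3 lines, 118 of them shared with the main 123. Limma's count of 0 genes held under 14 of 15 alternatives, among them the fit without the replicate block that ignores the pairing of transgenes within a line (0 genes, smallest adjusted p = 0.355). Median centring gave 1809 genes (1646 higher, 163 lower), as it leaves in place the trend of ratio with brightness that loess removes, and it shifted the median of all genes to 0.164. The count of genes at 2-fold in all 3 lines was 426 with the Feature Extraction log ratio (162 higher, 264 lower; 115 shared with the main genes), 419 with the series value table (110 shared) and 560 with median centring (529 higher, 94.5% against 33.3%; 68 shared). It was 565 at 1.5-fold, 19 at 3-fold and 187 to 381 with 1 line left out, where fewer lines have to meet the rule. In WM793 the count of 1864 became 3388 with the Feature Extraction log ratio, 3392 with the series value table, 4594 at 1.5-fold and 620 at 3-fold. In WM115 the count of 839 became 1938, 1930, 2588 and 211 in the same order, and 1452 with median centring. In A375 the count of 796 became 1957, 1949, 2718 and 239, and 1939 with median centring. The share of higher genes under median centring was 82.6% against 48.6% in WM793, 82.5% against 50.8% in WM115 and 87.5% against 43.1% in A375, and 32.7% in A375 with the strict filter. FOXD3 had a mean of 0.73 and ERBB3 of 1.08 (adjusted p = 0.0473; range 0.0473 to 0.623 over alternatives) under median centring. Camera's 4 lists became 2 with the Feature Extraction log ratio, 2 with the series value table, 0 with an estimated correlation and 0 by directional fry, while mixed fry, which asks whether genes change either way, called 19 of 26. The mitosis list was called under all alternatives but the estimated correlation (adjusted p = 0.833), directional fry (adjusted p = 0.366) and mixed fry (adjusted p = 0.142), but its median of -0.79 came to -0.244 under median centring and -0.405 without WM793. PGK1 reversed to 1.02 under median centring. The correlation between lines stayed between 0.428 and 0.573 (main 0.443), and the sign of the mean changed for 8 of 187 named genes with median centring and 1 to 4 with a line left out. Apart from what the alternatives' own construction shows, the cause was not tested. The slide as a block was not run, since there was 1 slide. Signal over background limits the dim genes, where normexp and the Feature Extraction signals differ most.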

Other observations

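The genes in this part were chosen after their values were seen, and no gene named here passed limma's test over all genes. In WM793, WM115 and A375, HLA-DRA had log2 ratios of 1.02, 1.42 and 0.88, HLA-DMB 0.62, 1.48 and 1.20, and HLA-DPA1 0.98, 1.75 and 0.63. CD74, the invariant chain that binds class II molecules, had 0.93, 1.88 and 0.33. CIITA, the transactivator of class II genes, had 0.61, 1.4 and 0.88. HLA-DQA1 was higher in WM115 (2.38) and A375 (1.07) but not in WM793 (-0.22), being well above background on 2 arrays, and HLA-DOB was slightly lower in all 3 lines (mean -0.23 ± 0.05, n = 3), though the mean of its probes gave 0.51. Probes of the HLA-DR and HLA-DQ genes can bind transcripts of their close relatives, so these values are not independent.

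Other genes at least 2-fold in 1 direction in all 3 lines included EPAS1, a hypoxia-inducible transcription factor, with a mean of 1.79, the potassium channel gene KCNK5 with 1.80, the keratin KRT80 with 2.06 and the elastic fibre gene FBLN5 with 1.55. In LacZ cells KRT80 was well above background on 2 of 3 arrays and FBLN5 on 1, so their ratios are uncertain, with Feature Extraction means of 3.07 and 2.74. Among lower genes were the transcription factor genes TBX2 (-1.43) and EYA1 (-1.79, with FOXD3 cells well above background on 2 arrays), the corepressor TLE4 (-1.89), the BMP and activin regulators BAMBI (-1.45) and FST (-1.44), the proteoglycan SDC2 (-1.38), the signalling adaptor EPS8 (-1.81) and the receptor activity-modifying protein RAMP1 (-1.90). BNIP3, which like PDK1 is a target of hypoxia-inducible factors, was lower at -1.18, -1.28 and -1.56, whereas EPAS1 was higher at 2.38, 1.34 and 1.64. Under median centring the mean of BNIP3 came to -0.20 and that of BAMBI to -0.34.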
